A study of Mus musculus with 8 samples.

How the data were processed

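The assay was ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, on microglia sorted by flow cytometry from mouse cortex. Per the labels, mice at postnatal day 30 received interleukin-33 (IL-33) or vehicle into the cerebral ventricle of one side, and tissue was taken 4 hours later. There were 4 mice per treatment, 2 of them female. Each library came from a separate mouse, per the labels.

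The deposited file held one value per peak and library for 104981 peaks. Per the file headers, the authors started from a list of reproducible (IDR) peaks and counted tags over the whole of each peak with HOMER annotatePeaks on mm10, with at most 3 tags per position. The deposited values were a signal, the tags in a peak scaled to 10000000 tags per library, per the file headers. The table also carried the authors' score of each merged peak, with a lowest value of 540, and it was not used in any test. A further deposited column named the list or lists that held each peak, vehicle, IL-33 or both, so peaks had been called per group and merged. Genomic annotation and nearest transcription start site were those of HOMER in the same table, and the nearest start site is an assignment by distance, not evidence that a peak regulates the gene. The submitters' processing notes name Bowtie2, HOMER and DESeq2 without versions or roles, and the builds mm10 and GRCm38. Read trimming, duplicate removal, any shift of reads for the transposase and the versions of the tools were not given in the sources used here. Peaks were 200 to 2280 bp long, with a median of 274 bp. Coordinates are those of the deposited table, on mm10.

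Totals per library, per the file headers, ran from 35842688 to 43857673 tags. Every value was a whole multiple of the worth of 1 read, one mate of a pair, within 0.006 tags (100% of values), and 1 read was worth 0.114 to 0.139 scaled tags. A level of 3 reads, taken as the floor, was 0.342 to 0.418 tags. Wilson intervals (95%) of the share of tags in peaks and these floors cover counting error only.

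Columns of the table named the treatment group but not the mouse. The 8 columns were therefore used as 4 replicates per group under the columns' own numbers, and 0 other columns of values per sample were left aside. Sex was not read from the values, so the planned sex term, the planned female against male comparison and the planned treatment by sex interaction were not fitted. The fit without a sex term, planned as an alternative, took the place of the fit with one. Replicates were compared by correlation across peaks and by a chi-square test of reads before averaging.

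Levels were analysed as log2(tags + 1.155), the pseudocount being 10% of the median peak mean of 11.55 tags. This rule had been set for the case of a median under 20 tags. Peaks in the lowest 10% of means were left out (10501 peaks), which left 94480 peaks with a lowest mean of 4.3 tags. IL-33 was compared with vehicle in limma 3.58.1 (R 4.3.3; empirical Bayes without trend, two-sided, Benjamini-Hochberg over all peaks tested, threshold 0.05). Fold changes are on this log2 scale and understate the change of weak peaks. limma shrank every peak to one common spread, so the standard error of a log2 change was 0.34 at each peak, and the smallest p-values should not be read literally. One value per gene was made by summing the tags of all peaks assigned to it, as log2(sum + 5), for 16386 genes after the same filter, with a standard error of 0.28. The data were tested as deposited, without rescaling for the share of tags in peaks.

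A total of 18 gene lists with 406 entries, 376 of them measured, was fixed before the data were examined, together with the tests, most of the other settings and the rule for named genes. The table paired gene symbols with Entrez identifiers, and 18185 of 18207 genes matched the reference names. Lists were tested with camera in limma (preset correlation 0.01), with camera at an estimated correlation, and with fry, adjusted over the lists. The camera test compares a list with all other genes tested. The fry test asks whether a list's genes move on balance one way, and its Mixed form whether they change in either direction. Shares of genomic classes among changed peaks were compared with all other tested peaks by Fisher's exact test, adjusted over classes and directions.

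Named peaks were the 10 with the largest rise and the 10 with the largest fall, 1 per gene, among peaks past the threshold whose 4 IL-33 libraries all lay on one side of the 4 vehicle libraries. Predicted genes, microRNA genes and Rik clones were left out of these. Each list added the best peak of up to 3 genes with the smallest p, and Tlr2, Marco, Il1rl1, Nfkbia, P2ry12 and Xist were named in any case. A peak that this rule names is not reported here. Genes named from summed tags or as loci with many changed peaks, and the promoter peaks of Tlr2, Marco and marker genes, were chosen after their values were seen.

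The alternatives were other pseudocounts, filters, scalings, variance models, thresholds and peak assignments, and leaving out each library in turn. Alternatives chosen after seeing the data were the quasi-likelihood test of edgeR 4.0.16 on the recovered reads, a pseudocount of 5, a 2-fold limit, median-ratio scaling with IL-33 library 2 left out, and promoter peaks with an estimated correlation. The fits were tested on simulated data with the mean levels and library scales of the real data. Spread was set to one fixed value for all peaks and genes, not estimated from the libraries, and few features were changed. The rates below hold for these settings only. For IL-33 against vehicle, limma on peaks as deposited recovered 4.5% of 67 peaks changed 2-fold and 100% of those changed 4-fold or 8-fold, with 0 false calls among the remaining of 94482 peaks. With median-ratio scaling it recovered 77.6% of the 2-fold changes with 11 false calls, and edgeR with TMM 76.1% with 13. On summed tags of 16386 genes, limma as deposited recovered 22.7% of the 2-fold changes and 100% of the 4-fold changes. The camera test called 20 of 20 shifted lists and 0 of 340 unshifted lists. These lists were random genes that varied independently apart from library scale, so 0 of 340 is not a false call rate for the real lists. In the real libraries, splits that mixed the groups gave up to 6 lists at the preset correlation.

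The planned test of 16 transcription factor motifs needs the sequence of mm10, which was not used here. Values were read with data.table, version 1.17.8, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15.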

Results

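Open chromatin was profiled in microglia, the resident macrophages of the brain, from the cortex of 8 mice. The comparison was between 4 mice injected with IL-33, a cytokine of the interleukin-1 family that signals through the receptor ST2, and 4 mice injected with vehicle, at 4 hours. The question, per the series title, concerned pattern recognition by microglia in response to IL-33. Libraries held 35842688 to 43857673 tags, and levels are given as tags scaled to 10000000 per library. The share of tags in peaks was 26.5%, 27.9%, 20.8% and 26.5% in vehicle libraries 1 to 4 and 29.9%, 14.2%, 22.0% and 31.3% in IL-33 libraries 1 to 4. The means of 25.4% ± 3.15 and 24.3% ± 7.89 (SD, n = 4 each) did not differ by an exact permutation test (two-sided p = 0.857, smallest possible 0.0286). No pair of libraries matched within sampling noise, the lowest chi-square per degree of freedom within a group being 3.74. Correlations of log2 levels across peaks were 0.896 to 0.961 within groups and 0.804 to 0.853 between groups; peaks are not independent replicates. As deposited, the first principal component (42.9% of variance) left vehicle library 3 at -27.1 and IL-33 library 4 at -8.6. With median-ratio scaling, vehicle libraries lay between -112.5 and -100.1 and IL-33 libraries between 96.2 and 123.2 on the first component (59.8%).

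**Figure D1:**
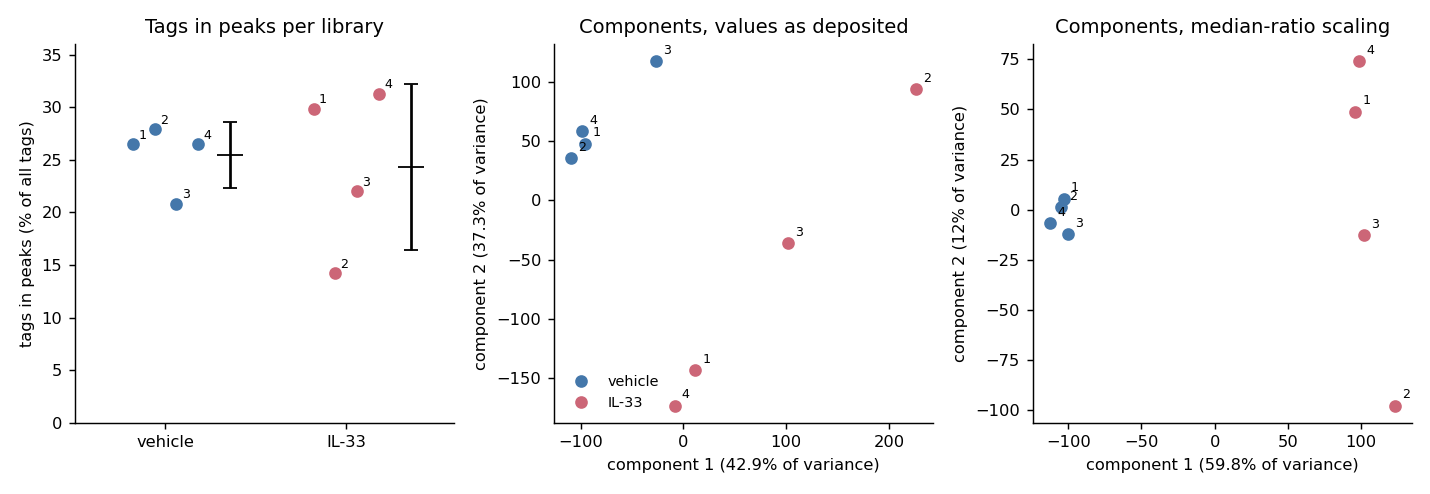
Share of tags in peaks per library (percent, points, with the group mean and SD, n = 4) and principal components of log2 levels as deposited and after median-ratio scaling. IL-33 library 2 held 14.2% of its tags in peaks, and the groups separated on the first component after scaling (59.8% of variance).

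Among the peaks that the naming rule admits, the largest log2 rise was at an intronic peak assigned to Gng7, a G protein gamma subunit (chromosome 10, 80967406 to 80967616). Its level went from 1.31 ± 1.03 to 65.7 ± 16.6 scaled tags (mean ± SD, n = 4 each, log2 change 4.82, limma, adjusted p = 3.51e-41). Intronic peaks rose at Mgll, the monoacylglycerol lipase gene (chromosome 6, 88737038 to 88737243; 1.14 ± 0.85 to 54.7 ± 13.6), and at Ikbke, which encodes a kinase of the NF-kB and interferon pathways (chromosome 1, 131276872 to 131277175; 3.17 ± 0.90 to 107 ± 28.2). The promoter of the zinc finger gene Zfp811 rose from 1.33 ± 0.29 to 63.0 ± 17.6 tags (chromosome 17, 32810694 to 32811110; log2 change 4.65). The largest log2 fall under the same rule was at an intergenic peak 30.4 kb from Socs6, a suppressor of cytokine signalling gene (chromosome 18, 88924420 to 88924759). Its level went from 125 ± 18.1 to 14.4 ± 8.12 tags (log2 change -3.21, limma, adjusted p = 1.01e-18).

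The other peaks among the 10 largest rises were assigned to Maf, Nfe2l1, Slc11a1, Cebpd, Dusp2 and Batf, with log2 changes of 4.47, 4.43, 4.42, 4.39, 4.39 and 4.36. Maf, Cebpd, Nfe2l1 and Batf encode bZIP transcription factors, Slc11a1 a phagosomal metal transporter and Dusp2 a MAP kinase phosphatase. The Maf peak lay 314.3 kb from the start site. After Socs6, the falls were at peaks assigned to Mapre3 (-2.99), Lsm6 (-2.98), Trp53i11 (-2.87), Gpr34 (-2.83), Kcnk2 (-2.74), Tmem114 (-2.62), Zc3h12c (-2.53), Dpt (-2.50) and Naaladl2 (-2.50). Many of these were also far from the start site: Tmem114 656.6 kb, Naaladl2 269.2 kb, Zc3h12c 205.6 kb, Kcnk2 157.9 kb, Dpt 114.9 kb and Lsm6 103.7 kb. Gpr34 encodes a lysophosphatidylserine receptor enriched in microglia; its peak, 14 kb upstream of the start site, fell from 29.8 ± 6.16 to 3.31 ± 1.36 tags (chromosome X, 13618659 to 13618941; adjusted p = 1.23e-14). These 20 peaks were chosen so that the 4 IL-33 libraries lay on one side of the 4 vehicle libraries. The choice of list peaks did not require this. It held in the best peaks of list genes named below with a rise or fall, except that of Mog. At peaks with vehicle levels near 1 tag the log2 change depends on the pseudocount, and so does the order of the peaks. Without a pseudocount, the ratio of the IL-33 to the vehicle mean was 50.18 at Gng7, 63.84 at Maf and 57.64 at Cebpd. For falls, the ratio of the vehicle to the IL-33 mean was 8.69 at Socs6 and 11.33 at Lsm6.

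**Figure D2:**
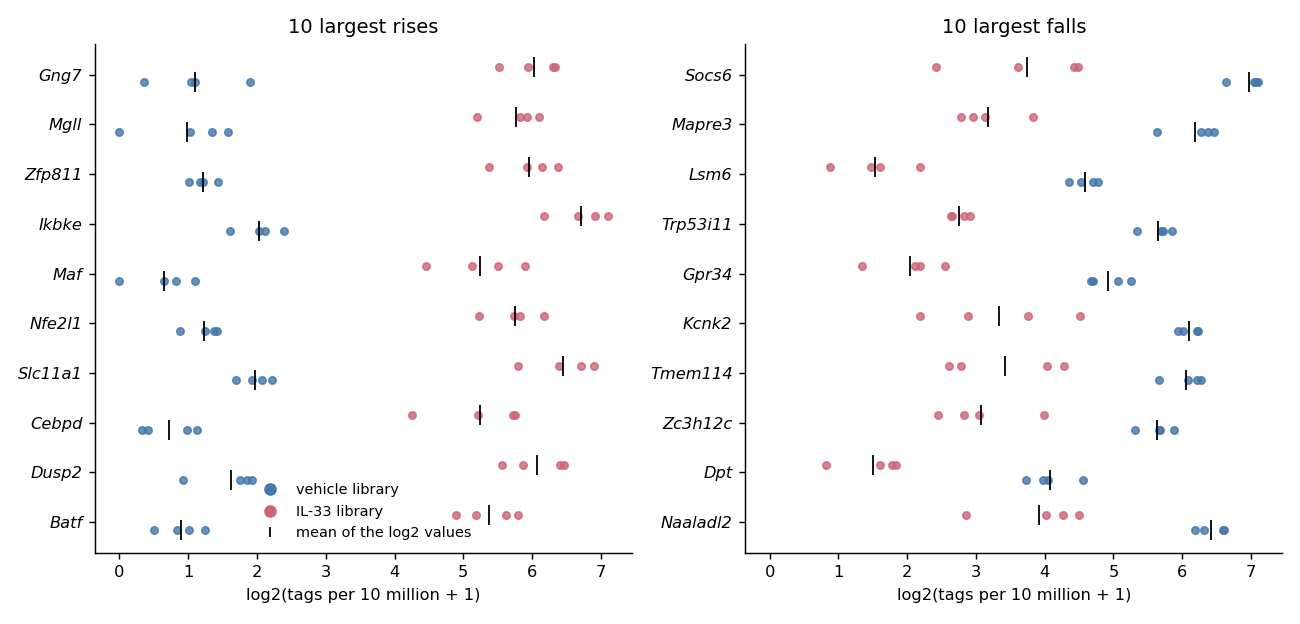
Levels of each library, as log2(scaled tags + 1), at the 10 peaks with the largest rise and the 10 with the largest fall, named by nearest gene, with bars at the group means of the log2 values. Gng7 rose from 1.31 to 65.7 mean tags and Socs6 fell from 125 to 14.4.

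Of 94480 peaks tested, 8058 rose and 4714 fell in limma, 13.5% of those tested. Raised peaks went from a median of 4.2 to 15.6 tags (median log2 change 1.41) and lowered peaks from 19 to 8.1 tags (-1.13). Raised peaks were assigned to 3939 genes and lowered peaks to 2702, and 840 genes had both. Large gains were more common than large losses: 1715 called peaks rose at least 4-fold and 90 fell at least 4-fold. Groups did not overlap at 9744 of the called peaks, and at 13.9% of all tested peaks, where chance gives 2.9%. Raised peaks were 63.1% of the changed peaks as deposited and 51.1% with quantile normalization (12782 raised and 12211 lowered), which shared 7738 raised and 4598 lowered peaks with the fit as deposited. Median-ratio scaling gave 14411 raised and 10226 lowered. Raised peaks numbered 13557 without IL-33 library 2. Without IL-33 library 4 lowered peaks outnumbered raised peaks, 8034 to 6197. Lowered peaks numbered 2547 without IL-33 library 3, and 2463, 2441 and 2697 without vehicle libraries 1, 2 and 4.

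**Figure D3:**
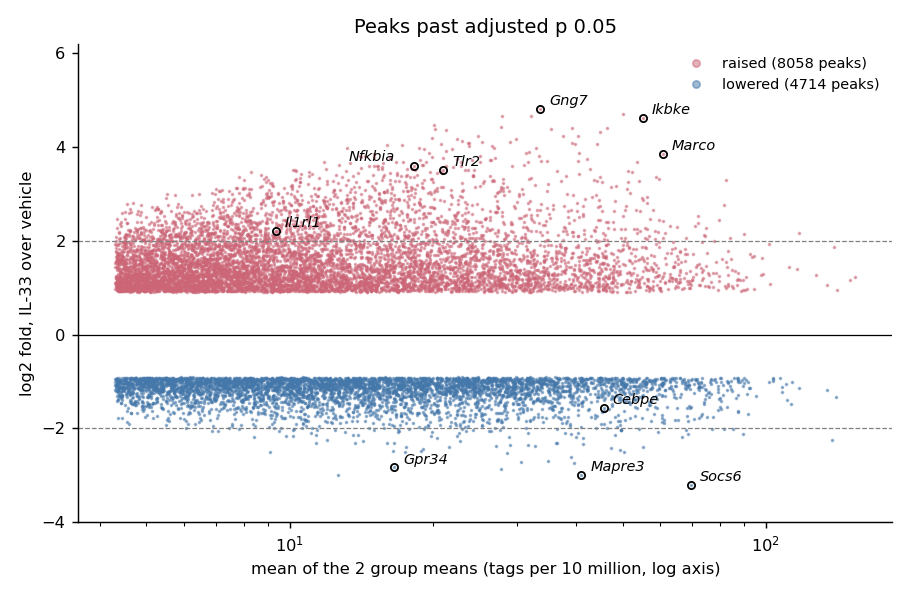
Log2 change, IL-33 over vehicle, against the mean level over the 8 libraries (scaled tags, log axis) for the peaks past adjusted p 0.05 in limma, each point a peak. There were 8058 raised and 4714 lowered peaks, and the Gng7 peak had the highest log2 change of the named peaks at 4.82.

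Changed sites lay away from promoters. Promoter peaks were 4.63% of raised peaks and 17.17% of the other tested peaks (373 peaks; odds ratio 0.234, 95% interval 0.21 to 0.26; Fisher's exact test, adjusted p = 2.41e-242). Among lowered peaks they were 4.12% against 16.73% (194 peaks; odds ratio 0.214, interval 0.184 to 0.247; adjusted p = 8.08e-154). Intergenic peaks were 37.88% of raised peaks against 30.66% (odds ratio 1.38) and 40.01% of lowered peaks against 30.82% (odds ratio 1.5). Introns held 51.95% of raised and 49.68% of lowered peaks, with odds ratios of 1.35 and 1.21. Neighbouring peaks are not independent, so these intervals are too narrow. Peaks were not matched for level either. Promoter peaks had a median of 46.5 tags with median-ratio scaling, whereas raised peaks had a median of 4.2 and lowered peaks of 19 tags in vehicle. How far level accounts for the promoter shares was not tested. Median distance to the nearest start site was 14.9 kb for raised, 29.8 kb for lowered and 9.7 kb for other peaks. Of tested peaks that the authors listed only under IL-33, 38.5% rose (4824 of 12530) and 14 fell. Of those listed only under vehicle, 21% fell (1307 of 6231) and 17 rose. Of those in both lists, 3217 rose and 3393 fell out of 75719. These lists were made from the same libraries and are not independent evidence of direction.

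Summed over the peaks of each gene, tags rose at 240 genes and fell at 202 of 16386 in limma, 54.3% raised as deposited, a majority that depended on single libraries and on scaling. Zfp811 (log2 change 2.94), Pdpn, which encodes podoplanin (2.65), the lipopolysaccharide-degrading enzyme gene Aoah (2.33) and the chemokine gene Ccl22 (2.25) rose, from 6.8 ± 1.5 to 87.8 ± 25 tags for Zfp811 and from 41.1 ± 9.3 to 230 ± 67.1 tags for Aoah (n = 4 each). The potassium channel gene Kcnk2 fell from 121.7 ± 14.5 to 33.3 ± 19.6 tags (log2 change -1.86, adjusted p = 2.4e-08). With median-ratio scaling 1934 rose and 2556 fell (43.1% raised), and with quantile normalization 2148 rose and 2119 fell (50.3%). The median log2 change of all genes was -0.17 as deposited, -0.03 with quantile normalization, -0.07 with median-ratio scaling and -0.06 with equal column sums, and list medians are given relative to that median. The 442 changed genes became 1495 without IL-33 library 2 (1166 raised, 329 lowered), 682 without IL-33 library 4 (177 raised, 505 lowered), 462 without IL-33 library 1 (160 raised, 302 lowered), 226 without IL-33 library 3, and 217, 233 and 226 without vehicle libraries 1, 2 and 4. Without vehicle library 3, 149 genes rose and 155 fell.

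Peaks of the NF-kB pathway and of cytokine genes rose at the highest rates of the fixed lists. NF-kB is a transcription factor activated by receptors of the interleukin-1 family. Of 374 tested peaks assigned to the 26 NF-kB genes, 142 rose (38%) and 4 fell, against 8.53% and 4.99% of all tested peaks, and 22 of the genes had a raised peak. The best peaks were at Tnip1, an inhibitor of NF-kB signalling (3.57 ± 1.41 to 75.8 ± 12.6 tags, log2 change 4.06), at Nfkb1 (3.92) and at the ubiquitin ligase gene Birc3 (3.78). An intergenic peak 25.6 kb from Nfkbia, which encodes the inhibitor IkB-alpha, rose from 1.98 ± 1.68 to 34.5 ± 9.88 tags (chromosome 12, 55466974 to 55467210; log2 change 3.59, adjusted p = 2.37e-23), and 12 of the 27 tested Nfkbia peaks rose. In summed tags Tnip1 (1.5), Bcl3 (1.14) and Birc3 (1.05) rose and 23 genes did not pass, the same 3 when adjusted over the list alone. The list median lay 0.66 above all genes (camera, adjusted p = 4.65e-14; adjusted p = 0.953 with an estimated correlation).

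Among 30 cytokine and chemokine genes, 10 rose in summed tags and none fell, and 15 rose when adjusted over the list alone. They included Ccl22 (2.25), the interleukin-1 receptor antagonist gene Il1rn (2.04), Cxcl16 (1.73) and Tnf (1.30). Of 230 tested peaks 101 rose (43.9%) and 3 fell. An intergenic peak near Cxcl16, a chemokine for T cells, rose from 2.21 ± 1.16 to 57.5 ± 11.3 tags (log2 change 4.17), one near Il10, an anti-inflammatory cytokine gene, from 3.65 ± 2.10 to 74.7 ± 18.1 (4.09), and one near Ccl12 from 1.94 ± 1.46 to 40.02 ± 13.5 (3.78). The list median lay 0.79 above all genes (camera, adjusted p = 1e-32; adjusted p = 0.621 with an estimated correlation). The fry test gave adjusted p = 0.378 for movement on balance one way and 0.0226 for change in either direction. Of the 18 lists, 6 passed camera at the preset correlation and 0 passed with an estimated correlation. With median-ratio scaling the estimated correlation gave adjusted p = 0.0577 for both the NF-kB and the cytokine list.

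**Figure D4:**
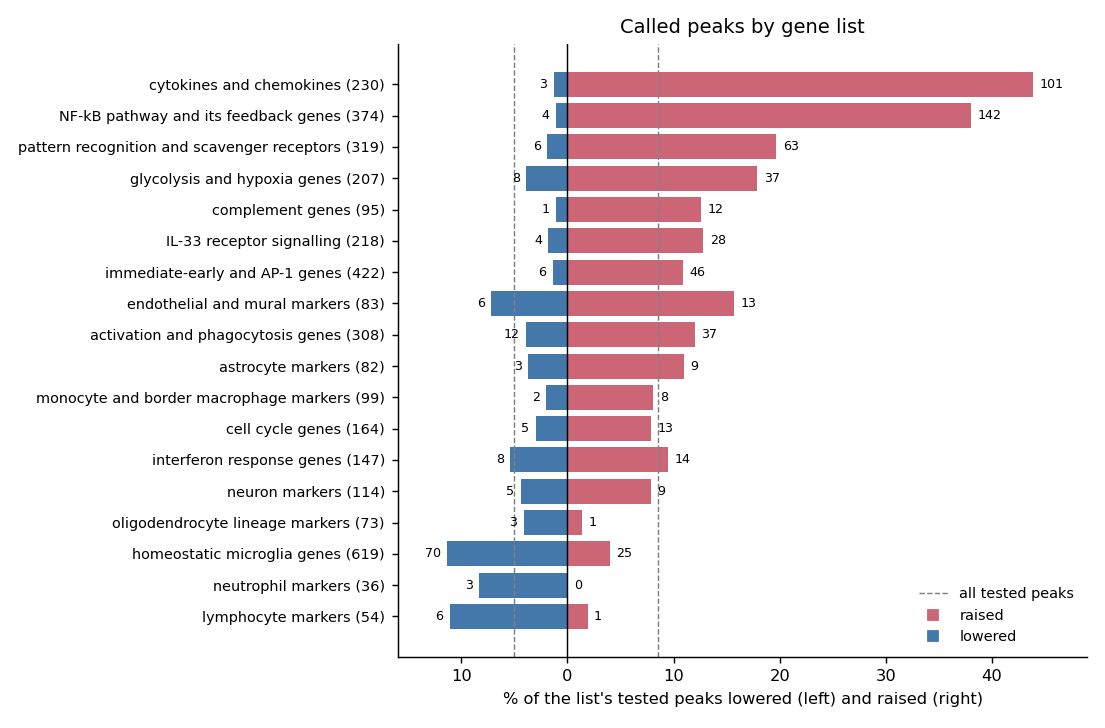
Percent of the tested peaks of each fixed gene list that rose or fell with IL-33 (limma, adjusted p 0.05), with dashed lines at the shares of all tested peaks, 8.53% raised and 4.99% lowered. Cytokine and NF-kB peaks rose at 43.9% and 38%, and homeostatic microglia peaks fell at 11.3%.

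Pattern recognition receptor genes had raised peaks, among them Tlr2, a receptor for bacterial lipoproteins, and Marco, a scavenger receptor. The best Tlr2 peak, intergenic and 3.4 kb from the start site (chromosome 3, 83844846 to 83845134), rose from 2.35 ± 1.38 to 39.6 ± 15.7 tags (log2 change 3.51, adjusted p = 2.59e-22). The Tlr2 promoter rose from 56.5 ± 9.73 to 114 ± 27.2 (0.98, adjusted p = 0.0304), and 6 of 20 tested peaks rose. An intergenic peak 27.7 kb from Marco rose from 6.43 ± 0.80 to 115 ± 41.3 tags (chromosome 1, 120532541 to 120532885; log2 change 3.86, adjusted p = 6.5e-27), and the peak in its 5′ untranslated region rose from 8.43 to 52.9 (2.48). Of the 21 tested Marco peaks 9 rose and 1 fell. At Tlr1, the partner of Tlr2 in lipoprotein recognition, the best peak rose from 6.92 ± 1.24 to 80.2 ± 22.2 (3.30), with 10 of 15 tested peaks raised. Of 35 measured genes 5 rose in summed tags, Cd36 (1.91), Fpr1 (1.74), Clec4d (1.16), Tlr1 (1.09) and Fpr2 (0.96), and none fell; 7 rose when adjusted over the list alone, which added Tlr2 (0.81) and Marco (0.73). Of 319 tested peaks 63 rose (19.7%) and 6 fell. The list median lay 0.23 above all genes (camera, adjusted p = 9.4e-07; adjusted p = 0.953 with an estimated correlation).

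**Figure D5:**
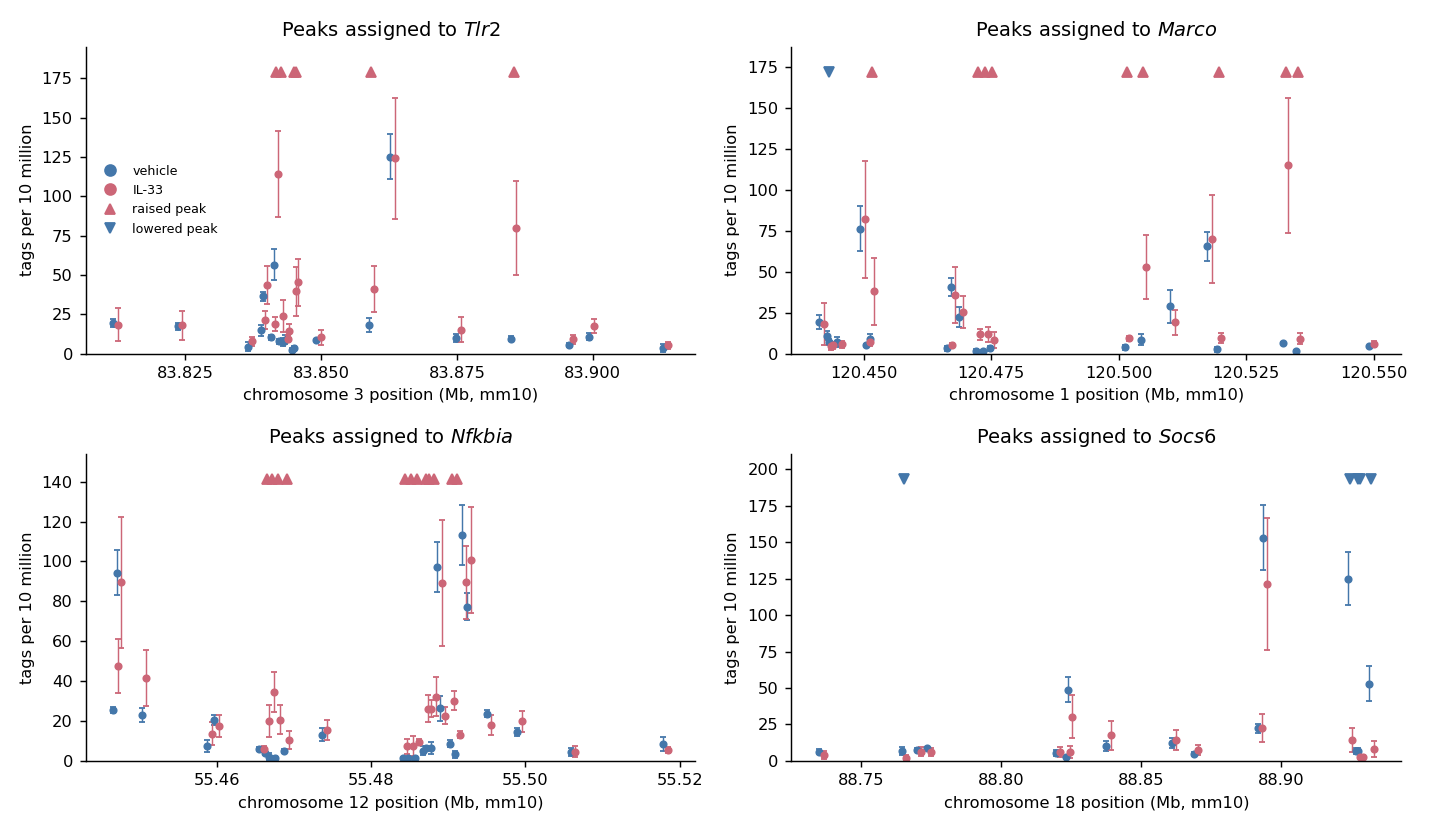
Mean level of each peak (scaled tags, ± SD, n = 4) in vehicle and IL-33 libraries against mm10 position for the tested peaks assigned to Tlr2, Marco, Nfkbia and Socs6, drawn slightly apart for legibility, with triangles at peaks past adjusted p 0.05 in limma. At Tlr2, 6 of 20 tested peaks rose, and the Socs6 peak with the largest fall went from 125 to 14.4 tags.

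Genes of the IL-33 receptor pathway and immediate-early genes had raised peaks, and none passed in summed tags. Il1rl1 encodes the IL-33 receptor ST2, and 1 of its 15 tested peaks, intergenic at 17 kb, rose from 2.47 ± 0.90 to 16.2 ± 7.47 tags (chromosome 1, 40412438 to 40412737; log2 change 2.21, adjusted p = 4.67e-09). Irak3, which encodes a negative regulator of this pathway (3.09), and the kinase gene Mapkapk2 (2.95) also had raised peaks. Of the 22 receptor pathway genes 16 had a raised peak. Of their 218 peaks 28 rose (12.8%) and 4 fell (1.8%), against 8.53% and 4.99% of all tested peaks. In summed tags 0 of the 22 genes passed, also when adjusted over the list alone (camera, adjusted p = 0.115). Among immediate-early and AP-1 genes, peaks rose that were assigned to Batf (0.90 ± 0.40 to 41.7 ± 11.7 tags), Fos (2.74) and Jun (2.54). Distances to the start site were 50.8 kb for the Fos peak and 226.4 kb for the Jun peak. Of 422 peaks of these 26 genes 46 rose (10.9%, near the 8.53% of all tested peaks) and 6 fell. In summed tags 0 genes passed, also when adjusted over the list alone (camera, adjusted p = 0.115). The median log2 change of the immediate-early list was -0.006 and its mean 0.011 as deposited, and its camera direction, relative to all genes, was up. With median-ratio scaling both lists passed (adjusted p = 0.00949 each; 0.254 each with an estimated correlation), and the immediate-early list passed with promoter peaks alone (adjusted p = 0.00063; 0.73 with an estimated correlation). At an unadjusted p under 0.05, 1622 of all genes differed in limma, and edgeR on the recovered reads called 4340 with TMM and 410 with total tags at adjusted p 0.05.

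Peaks of homeostatic microglia genes fell more often than they rose. Of 619 tested peaks 70 fell (11.3%) and 25 rose (4%), and 19 of 26 genes had a lowered peak. In summed tags Siglech, a sialic acid-binding receptor of microglia, fell from 573.9 ± 59.3 to 275.9 ± 99.9 (-1.12, adjusted p = 0.00498) and Crybb1 from 276.9 ± 43.4 to 144.8 ± 54.0 (-0.98), 24 genes did not pass, and Gpr34 (-0.88) was added when adjusted over the list alone. Single peaks rose that were assigned to Tgfbr1, a TGF-beta receptor gene (12.1 ± 2.99 to 98.3 ± 32.5 tags, log2 change 2.88; 39.1 kb from the start site), and to Csf1r, the receptor gene of a microglial growth factor (2.34; 22.4 kb). The best peak assigned to P2ry12, a purinergic receptor gene, lay 2.1 kb upstream of its start site in an exon of another transcript (chromosome 3, 59264898 to 59265183) and was 48.9 ± 8.57 in vehicle and 30.7 ± 13.6 in IL-33 libraries and did not pass (log2 change -0.74, adjusted p = 0.148). It passed with median-ratio scaling (-0.64, adjusted p = 0.00802) and without IL-33 library 4 (-0.98, adjusted p = 0.0358). The list median lay at -0.17 relative to all genes (camera, down, adjusted p = 0.0146; adjusted p = 0.953 with an estimated correlation).

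Activation and complement genes had raised peaks. Among activation and phagocytosis genes the best peaks were at the integrin gene Itgam (2.91 ± 1.16 to 29.7 ± 10.2 tags, log2 change 2.90), the cathepsin gene Ctsl (2.41) and the hyaluronan receptor gene Cd44 (2.29). Of 308 peaks 37 rose (12%) and 12 fell, but 0 of 32 genes passed in summed tags, also when adjusted over the list alone. The list median lay 0.23 above all genes (camera, adjusted p = 0.0339; adjusted p = 0.953 with an estimated correlation). Of 14 measured complement genes only C3, the central complement component, rose in summed tags (15.5 ± 3.9 to 36.4 ± 9.9 tags, log2 change 1.0), also when adjusted over the list alone. The C3 promoter rose from 2.37 ± 0.71 to 17.3 ± 4.65 tags (2.38), and a peak of the complement receptor gene C3ar1 rose (2.28). Itgam belongs to both lists. The complement list median also lay 0.23 above all genes (camera, adjusted p = 0.0333; adjusted p = 0.953 with an estimated correlation). Neither list passed without vehicle library 3 (adjusted p = 0.055 for both), with no filter (0.059 for both) or with array weights (0.0594 for activation and 0.493 for complement). The activation list did not pass without IL-33 library 4 (adjusted p = 0.0864), nor the complement list with the lowest 30% of genes left out (0.0931).

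Interferon response, glycolysis and cell cycle genes did not pass as lists. Among 25 interferon genes Ifit3, an interferon-induced antiviral gene, fell in summed tags (91.7 ± 12.5 to 41.1 ± 17.4, log2 change -1.15), over all genes and adjusted over the list alone; 14 of 147 peaks rose and 8 fell (camera, adjusted p = 0.642). Single interferon list peaks rose at Bst2 (3.41) and Irf8 (3.10). Of 207 peaks of glycolysis and hypoxia genes 37 rose (17.9%) and 8 fell, and 22 of those raised were at Pfkfb3, a regulator of glycolysis, whose best peak rose from 0.89 ± 0.50 to 33.5 ± 13.5 tags (4.04). The promoter of Acod1, the itaconate-producing enzyme gene, rose from 0.88 ± 1.13 to 15.6 ± 8.41 (3.03), and an intronic Pkm peak rose (2.77), from 0.36 tags, near the value of 3 reads. None of the 19 glycolysis genes passed in summed tags or over the list alone (camera, adjusted p = 0.427). Cell cycle genes had 13 raised and 5 lowered of 164 peaks, with rises at Cdk6 (2.46; 191.6 kb from the start site), E2f2 (1.79) and Cdkn1a (1.53). In summed tags 0 of 22 genes passed either way (camera, adjusted p = 0.858). The glycolysis median (-0.016) and mean (-0.03) were below 0 as deposited while the test was up relative to all genes. For cell cycle genes the median lay at -0.04 relative to all genes while the test was up, and the direction turned with scaling.

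Markers of other cell types were measured beside these groups. Of 99 peaks of monocyte and border macrophage markers 8 rose and 2 fell, with rises at Ccr1 (2.51), Clec12a (2.27) and Vcan (2.27; 149.8 kb from the start site). In summed tags 0 of 16 genes passed (adjusted p = 0.858). Of 36 neutrophil marker peaks 0 rose and 3 fell, among them the promoter of Cebpe, a granulocyte transcription factor gene (68.5 ± 11 to 22.7 ± 6.10 tags, log2 change -1.56), and an intronic Csf3r peak (-1.15), and 0 of 7 genes passed (adjusted p = 0.642). Lymphocyte markers had 1 raised and 6 lowered of 54 peaks, with Klrb1c raised (1.51) and Il7r (-1.48) and Cd79b (-1.29) lowered, and 0 of 12 genes passed (adjusted p = 0.858). The Csf3r peak did not pass without vehicle library 1 (-1.02, adjusted p = 0.0715) or 2 (-1.03, adjusted p = 0.068). Counts for these 3 lists were also 0 when adjusted over the list alone. With promoter peaks alone, the lymphocyte list passed, with a median 0.41 above all genes (adjusted p = 0.000264), as did the neutrophil list, with a median of -0.28 (adjusted p = 0.00203); neither passed with an estimated correlation (0.444 for both).

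Among cells of the brain and its vessels, 9 of 114 neuron marker peaks rose and 5 fell, with Camk2a (1.45) and Bcl11a (1.84) raised and Syt1 lowered (72.2 ± 14.9 to 30.9 ± 19.6 tags, -1.44). This Syt1 peak was 286 kb from the start site. Syt1 was the only neuron gene of 11 to fall in summed tags (-0.99), 2 fell when adjusted over the list alone, and the list did not pass (adjusted p = 0.858). The neuron list median lay 0.08 above all genes while its mean of -0.165 as deposited and its test were down, and its direction turned with scaling. Astrocyte markers had 9 raised and 3 lowered of 82 peaks, with Slc1a2 (2.46), Slc1a3 (2.15) and Slc7a10 (1.67) raised, and 0 of 13 genes passed (adjusted p = 0.858). Oligodendrocyte lineage markers had 1 raised and 3 lowered of 73 peaks, at Mbp (1.25), Opalin (-1.74) and Mog (-0.93, adjusted p = 0.0441, with overlapping groups), and 0 of 11 genes passed (adjusted p = 0.677). With promoter peaks alone the oligodendrocyte list passed, with a median 0.32 above all genes (adjusted p = 0.0119; 0.606 with an estimated correlation). For astrocyte and oligodendrocyte genes no gene passed over the list alone either. Endothelial and mural markers had 13 raised (15.7%) and 6 lowered of 83 peaks. The best peaks rose at Cldn5 (3.09), Flt1 (13.9 ± 4.37 to 86.1 ± 23.4 tags, 2.53) and Pecam1 (2.51), and the lowered peaks were at other genes of the list. Cldn5, a tight junction gene, rose in summed tags (1.11), the other 10 genes did not pass, and over the list alone 2 rose and 1 fell. The endothelial list did not pass as deposited (adjusted p = 0.0606) and passed with median-ratio scaling (adjusted p = 0.0242; 0.203 with an estimated correlation), with equal column sums (0.0307), with pseudocount 20 (0.0386) and without IL-33 library 2 (0.0418) or 3 (0.0417). The median and mean of the lymphocyte, astrocyte and oligodendrocyte lists were below 0 as deposited while their tests were up relative to all genes. Mog did not pass without any one of IL-33 libraries 1, 2 and 3 and vehicle libraries 1, 2 and 4 (log2 change -0.95, -0.64, -0.89, -0.88, -0.93 and -0.88), nor Mbp without vehicle library 4 (1.03). With a pseudocount of 20 the peaks of Bcl11a (adjusted p = 0.0514), Syt1 (0.0567), Slc1a2 (0.0507), Mbp (0.0805) and Mog (0.13) did not pass.

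Females and males were not compared, because the columns named no mouse and sex was not read from the values. Tags on 9 informative Y chromosome peaks came to 165 or more in 2 of 4 libraries of each group, the number of males the labels give, and to 0.25 or less in the others. These peaks were chosen from the same values, without regard to group, as Y peaks nearly free of tags in several libraries. Totals near 0 in some libraries were therefore partly built in. Over all Y chromosome peaks the totals ran from 202.1 to 521.6 tags. The Xist peak, in the gene of the RNA that silences an X chromosome, was 18 ± 3.86 in vehicle and 16.0 ± 6.11 in IL-33 libraries (chromosome X, 103477555 to 103477762; log2 change -0.22, adjusted p = 0.768).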

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

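The tests in this part were set out before their results were seen, except the calculations of the added cells that raised peaks and neutrophil markers would need, and of the tags held by called peaks, which were chosen only after those results had been seen. In groups of 4 libraries, 10 of 150 had one value far from the other three (6.7%), and chance gives about 1 in 20. IL-33 library 2 had 42411261 tags against 39223270 to 39441210 in the other IL-33 libraries. The Socs6 peak held 98.0 tags in vehicle library 3 against 131.5 to 136.2 in the other vehicle libraries. The Birc3 peak held 0 tags in vehicle library 4 against 1.15 to 1.25, and the Mapkapk2 peak 0.84 against 1.92 to 2.11 in the same library. In vehicle library 2 the C3 peak held 3.43 tags against 1.95 to 2.05, the Klrb1c peak 7.93 against 5.12 to 5.58, and the Nfkbia peak 4.49 against 1.02 to 1.26. In IL-33 library 4 the Bst2 peak held 46.1 tags against 27.2 to 30.2 and the Il7r peak 5.58 against 3.54 to 3.82. The E2f2 peak held 8.13 tags in IL-33 library 2 against 14.7 to 15.7.

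The groups were compared with all 35 splits of the 8 libraries into groups of 4. For changed peaks only 1 split, the real one, gave as many (12772, highest other 31). For changed genes in summed tags again 1 of 35 gave as many (442, highest other 158). Both argue against chance only as far as 35 splits allow. The other splits mix IL-33 and vehicle libraries, so any treatment difference widens their spread. The gap in counts therefore does not measure the strength of the evidence. For gene lists past the threshold at the preset correlation 4 of 35 gave as many (6; highest other 6), so chance cannot be excluded for the number of lists.

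Peaks raised at least 4-fold outnumbered peaks lowered at least 4-fold, 1715 to 90. If the unequal shares of tags in peaks were the cause, quantile normalization should even the numbers out, but the ratio there was 14 (1488 to 106). If background tags hid losses at weak peaks, peaks with a higher group mean of at least 30 tags should be balanced, but their ratio was 9.64 (559 to 58). Both values argue against these explanations as the whole cause. An opening of new sites by IL-33 that exceeds closing at 4 hours is a candidate explanation, found and tested on the same libraries. The tested set was itself uneven, with 12530 peaks that the authors listed only under IL-33 and 6231 only under vehicle. The IL-33 only peaks made up 59.9% of all raised peaks. Among peaks in both lists, at any fold past the threshold, gains did not outnumber losses (3217 raised, 3393 lowered). How far the makeup of the peak list accounts for the excess of large gains was not tested.

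IL-33 library 2 held 14.2% of its tags in peaks. A weaker response of that mouse was argued against, since its median log2 change at peaks called from the other libraries was 1.12 with median-ratio scaling, beside 1.11, 1.12 and 1.18 for the others. At the 5000 peaks with the smallest differences between groups its level was 0.486 of that of the other IL-33 libraries (quartiles 0.412 and 0.564), beside 0.513 for all tags in peaks. Called peaks held 10.2% of the tags in peaks of the other IL-33 libraries, so this value was close to fixed by the low share and says nothing of its cause. Whether the share came from the sort, the transposition or the animal was not tested.

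Peaks near NF-kB and cytokine genes rose, which a response of microglia or added cells of another kind could give. For another myeloid cell type, the 43 promoter peaks of 24 homeostatic genes had a median log2 change of -0.16 (standard error 0.095; range -1.94 to 1.93), and the bound of -0.3 set beforehand would have excluded it. At the highest level of any peak (490 tags), the median gain of 12.6 tags over 243 raised peaks would need 2.6% of added cells. That share would change the homeostatic promoters by -0.04. The largest gain would need 26.6%, a change of -0.45, so the values go against added cells as the only source of that gain. Both shares are the smallest possible, because added cells less open than 490 tags at a peak would need a larger share. How open the raised peaks are in such cells was not measured, so the median gain does not decide. Both changes assume that added cells are closed at the homeostatic promoters, which was not measured either. A share of another myeloid type therefore cannot be told apart from a response of microglia. Of 9 promoter peaks of monocyte and border macrophage markers 1 rose (Ccr1, 1.02) and 1 fell (Pf4, -1.38). Neutrophils also stay open: 0 of 6 promoter peaks of their markers rose and 1 fell, and fewer than 50% raised had been set as excluding them. However, S100a8 (3.8 tags in vehicle, 6.2 in IL-33) and Mmp8 (3.9 and 8.3) were weak. Csf3r (72.3 and 65.7) and Cebpe (68.4 and 22.7, log2 change -1.56) were already open in vehicle. The answer turns on how open these promoters are in neutrophils, which was not measured. A share of 2.6% would have raised 0 of the 6 past the smallest called rise at the median promoter level of 46.5 tags, a level chosen after the result. At 490 tags it would have raised 3 of the 6.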

How the results depend on the processing

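The tests on recovered reads with edgeR, the pseudocount of 5, the 2-fold limit and the joint settings of median-ratio scaling without IL-33 library 2 and of promoter peaks with an estimated correlation were chosen after seeing the data; the others were planned. The promoter shares stayed on the same side of the threshold in all 21 settings run for each direction. Of 1738 combinations of a named peak and a setting 1714 kept their call and direction, 16 lost and 6 gained a call and 2 turned, and 65 of 73 named peaks kept theirs throughout. The cause of the changes below was not tested, except that fewer peaks entered with the most common width (272 bp) and with promoter peaks alone. Weak peaks rest on few reads. In simulated data with few changed peaks the test as deposited missed most 2-fold changes. That rate does not carry over to the real data, where many more peaks changed and the adjusted threshold was less strict. Of the 12772 peaks called there, 10771 changed at least 2-fold, so some changes just below 2-fold were also called. All peaks shared a standard error of 0.34, so a call amounted to a limit on the log2 change. At peaks assigned to Nfkbia, a log2 change of 0.928 passed in limma (adjusted p = 0.0457) and 0.825 did not (adjusted p = 0.0894). Changes well below 2-fold were therefore not called.

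Peaks changed, raised and lowered numbered 6039, 4158 and 1881 with pseudocount 20; 24993, 12782 and 12211 with quantile normalization; 24637, 14411 and 10226 with median-ratio scaling. They numbered 24545, 14736 and 9809 with equal column sums, 27723, 19941 and 7782 with array weights (whose fit stopped before its tolerance was reached), and 101, 62 and 39 with the most common width. With edgeR and TMM they were 27289, 16132 and 11157, and with median-ratio scaling without IL-33 library 2 they were 22618, 13453 and 9165. Genes changed, raised and lowered numbered 4267, 2148 and 2119 with quantile normalization, 4490, 1934 and 2556 with median-ratio scaling, and 4440, 2030 and 2410 with equal column sums. They numbered 228, 124 and 104 with the lowest 30% left out, 10600, 8084 and 2516 with array weights, and 156, 89 and 67 with promoter peaks alone. With edgeR they were 4340, 2454 and 1886 with TMM and 410, 268 and 142 with total tags, and with median-ratio scaling without IL-33 library 2 they were 4371, 2043 and 2328. With pseudocount 20, 115 genes were lowered. Lists past the threshold numbered 10 with promoter peaks alone, which added the immediate-early, lymphocyte, neutrophil and oligodendrocyte lists, and 0 with an estimated correlation, over all peaks or promoter peaks.

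Leaving out each library in turn gave 9165 to 17644 changed, 6080 to 13557 raised and 2441 to 8034 lowered peaks, 217 to 1495 changed, 144 to 1166 raised and 60 to 505 lowered genes, and 4 to 7 lists. The highest raised counts came without IL-33 library 2 (13557 peaks, 1166 genes) and the highest lowered counts without IL-33 library 4 (8034 peaks, 505 genes). Lowered peaks numbered 2547 without IL-33 library 3 and 2463, 2441 and 2697 without vehicle libraries 1, 2 and 4. Changed genes numbered 682 without IL-33 library 4, 226 without IL-33 library 3, and 217, 233 and 226 without vehicle libraries 1, 2 and 4, and raised genes 149 without vehicle library 3.

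Directions that turned concerned no list or peak past the threshold. List medians relative to all genes, where the direction of the test turned, were -0.02 with pseudocount 1, -0.02 with quantile normalization and -0.07 without vehicle library 1 (to 0.09 with another library left out) for astrocyte markers. For cell cycle genes they were -0.02 with quantile normalization, -0.03 with median-ratio scaling and with equal column sums, and -0.02 with median-ratio scaling without IL-33 library 2. For neuron markers they were 0.03 with quantile normalization, 0.07 with median-ratio scaling, with or without IL-33 library 2, and with equal column sums, 0.10 with no filter, 0.08 within 100 kb and 0.12 with promoter peaks. For monocyte and border macrophage markers they were -0.0043 with pseudocount 20, 0.05 with the lowest 30% left out and 0.02 with median-ratio scaling without IL-33 library 2. Neutrophil markers were at 0.18 with no filter, lymphocyte markers at 0.04 with the lowest 30% left out and interferon genes at 0.01 with promoter peaks. The Xist peak was at 0.23 with array weights and ran from -0.40 to 0.06, the latter without IL-33 library 3, when single libraries were left out.

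Planned but not run were the sex term, the female against male and interaction tests and all their alternatives, the motif tests and their alternatives, and DESeq2, which was planned for raw counts. The plan numbered vehicle libraries 5 to 8 and the columns 1 to 4. No paired analysis was possible because the labels number the mice of the groups differently and the columns name no mouse.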

Other observations

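The 5 gene lists of this part, the odds ratios within deciles of level and the lists of loci were chosen only after results had been seen; the odds ratio for LTR repeats in raised peaks and the count of genes with many raised peaks were tests set out before. Raised peaks gathered at some loci. Leaving out predicted, Rik and microRNA genes, the genes with the most were Pik3r6, a regulatory subunit of PI3 kinase gamma (25 of 38 tested peaks raised), Pfkfb3 (22 of 49), the ETS factor gene Etv6 (20 of 68), and Nfkbiz (20 of 38) and Tnfaip3 (18 of 35), both regulators of NF-kB. At Ccr7, a chemokine receptor gene for migration to lymph nodes, 11 of 15 rose, at Il12b 12 of 21 and at Ccl4 10 of 12. Lowered peaks gathered at Ifitm10 (21 of 36), Khdrbs3 (17 of 23), Prim2 (15 of 18), Rbfox1 (15 of 50), Siglech (15 of 24) and Cln8 (14 of 31).

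Further groups were measured as lists. Among 17 extracellular matrix protease genes and inhibitors Adamts4, an aggrecan-cleaving protease gene, rose in summed tags (1.03). Mmp19 (0.88) was added when adjusted over the list alone. Of 95 peaks 10 rose (10.5%) and 1 fell, against 8.53% and 4.99% of all tested peaks. The camera test gave adjusted p = 0.00606, with 0.918 at an estimated correlation and 0.0469 at that correlation and median-ratio scaling. Among 18 MAPK phosphatase and SOCS genes Dusp2 rose (1.5) and Socs6 fell (-0.92), with 37 of 217 peaks raised and 12 lowered (adjusted p = 0.0672). Among 20 antigen presentation genes Cd40, a costimulatory receptor gene, rose (1.21), with 13 of 107 peaks raised and 0 lowered (adjusted p = 0.0672). For 20 lipid and cholesterol handling genes 21 of 206 peaks rose (10.2%) and 6 fell (camera, adjusted p = 0.225). For 20 TGF-beta and SMAD genes 36 of 360 rose (10%) and 17 fell (camera, adjusted p = 0.674). In either list 0 genes passed the threshold over all genes in limma. When adjusted over the list alone, Ch25h (0.85) rose in the lipid list.

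The hypothesis that raised peaks share a nearest gene more often than chance was tested against 1000 random draws of as many tested peaks. There were 341 genes with 5 or more raised peaks, above the highest of the draws (134), and 126 with as many lowered peaks, above 34. This is in line with groups of neighbouring sites that open or close together, and the draws did not match peaks for their level or their distance to genes.

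The hypothesis that raised distal peaks overlap LTR repeats more often than unchanged distal peaks was met with an odds ratio of 1.29 (8.64% against 6.82%, Fisher's exact test, adjusted p = 5.73e-08), and 1.25 within deciles of level. Lowered distal peaks had an odds ratio of 1.34 (adjusted p = 9.22e-07), so the excess was not particular to raised peaks. For LINE repeats the odds ratio was 1.70 in raised and 1.42 in lowered distal peaks, and for DNA repeats 1.77 and 1.19. Other classes lay below 1: SINE repeats at 0.984 and 0.757, simple repeats at 0.491 and 0.837, and low-complexity sequence at 0.555 and 0.424. Reads that map to several repeat copies may add to the values above 1, and this was not tested.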
